A study of Mus musculus with 2 samples.

How the data were processed

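RNA longer than 200 nt from mouse embryonic day 11.5 hindbrain, 10 ng per library, was sequenced as total RNA in 2 biological replicates. Per the labels, RNA was extracted with the mirVana kit, a Smart-Seq protocol document applied, ERCC spike-ins were added and the assembly was mm10. A readme beside the tables gives the gene annotation as GENCODE M4. The aligner and the quantification tool are not given in the sources used here, nor are strand settings, so reads of overlapping or antisense genes may not be separable.

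For each library the authors deposited a gene table and a transcript table. Per the file headers, each holds an expected count, which is an estimated count that need not be whole, then TPM and FPKM, and lower and upper bounds of an interval around TPM, whose level is not given in the sources used here. In the transcript table the authors also deposited an isoform percent, the transcript's share of its gene. TPM is relative to all entries of a table, including the spike-ins, and FPKM to length and library size, as the deposited values show. The effective length in the deposited tables was the length minus 99 nt wherever it was above 0. Each gene table had 69691 entries: 43346 Ensembl genes, 97 spike-in entries (96 of them ERCC) and 26248 entries named by a number.

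Gene symbols, biotypes and GRCm38 coordinates (the same build as mm10) came from GENCODE vM21, matched on the Ensembl identifier without its version. Of 43346 identifiers 42462 matched, and the 884 unmatched held 0.189% of expected counts in pool 1 and 0.189% in pool 2. Coordinates are 1-based.

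Depth was 45340440 and 41261544 expected counts. Of ERCC entries, 89 and 90 had at least 1 read. At this depth the SD of log2 ratios between the pools was 0.94 for genes with 10 to 100 reads and 0.20 for genes with 1000 to 10000 reads, against 0.68 and 0.11 for spike-ins with as many reads.

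Groups were taken from the labels, which place both samples in 1 group. No test between groups was possible. Values were compared as log2(TPM + 1), with a gene called detected at a TPM of at least 1. The pool ratio was log2((TPM + 1) in pool 2 over (TPM + 1) in pool 1). A set of 24 gene lists and 8 marker lists for other cell types was fixed before the data were examined, holding 307 distinct genes of which 305 matched the tables. Levels of lists are medians over members. To place a list's median pool ratio, 10000 random lists of the same size were drawn from the same 40 bins of mean expression (seed 11), and a list was singled out below percentile 2.5 or above 97.5. These percentiles describe the 2 libraries and are not p-values. Isoform shares were computed from transcript TPM for 12 genes.

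Genes named in the text were chosen by a rule fixed at the same time: in each list the 3 members with the highest and the 1 with the lowest mean TPM, all Hox genes, the 10 most abundant protein-coding nuclear genes, the 5 genes furthest apart between the pools in each direction among those with a mean TPM of at least 5, and list members over 1.5-fold apart with a mean TPM of at least 5. Some genes that the rule selects are not reported here. Further members (Clic6, Ddc, Fev, Slc6a4, Kcnq1ot1, Hotairm1 and Ddx3y) and the genes added in the closing observations, like the composition gene Gm42418, were named after their values were seen.

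The biological coefficient of variation was estimated with edgeR 4.0.16 in R 4.3.3 on expected counts rounded to whole numbers, with TMM scaling and filterByExpr, and DESeq2 1.42.0 gave size factors and gene-wise dispersions as alternatives. Other steps used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9. The steps were tested on simulated data for pool 2 against pool 1, with counts drawn for 43346 genes, of which 15436 had a simulated mean TPM of at least 1. Of genes raised 3-fold 90% were found over 2-fold apart, of those raised 4-fold 98%, of those raised 8-fold 100%, of those raised 1.5-fold 2%, and of unchanged genes 0.80%. All 5 lists raised 1.5-fold passed percentile 97.5. The self-test was changed after its first outcome in 2 ways. The first run had 9 of 100 unchanged lists outside the central 95%, and the number of lists was then raised to 400, which gave 24. A simulated coefficient of variation of 0.1 first came out as 0.147 over 17368 genes, because the 200 changed genes were included, and as 0.0993 over 17175 genes once they were left out. The value reported for the real libraries includes all genes that passed the filter, so it may be raised in the same way.

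Alternatives planned before the data were examined were a pseudocount of 0.1, FPKM in place of TPM, TPM rescaled over protein-coding nuclear genes, list means, other expression filters (none, 0.5, 5), TMM and DESeq2 scaling of expected counts, protein-coding genes only, and each replicate alone. TPM rescaled without spike-ins, random lists from protein-coding genes, a minimum of 100 reads and isoform shares of genes with more than 1 transcript were added after seeing the data. Readme files gave only the assembly and annotation and were not otherwise used. Entries named by a number and spike-ins were left out of gene counts and lists.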

Results

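Total RNA was profiled from the hindbrain of mouse embryos of strain B6NCrl at embryonic day 11.5. The series held 1 group of 2 biological replicates, each a pool of hindbrains from male and female embryos: pool 1 (replicate 1) combined 109 embryos and pool 2 (replicate 2) combined 88. Each library was made from 10 ng of RNA longer than 200 nt, with ERCC spike-ins, a set of synthetic RNAs of known sequence. Expected counts summed to 45340440 in pool 1 and 41261544 in pool 2, of which 41982915 and 36833678 lay on Ensembl genes. The labels state no question beyond profiling of this tissue, so the comparisons below are those the tissue and its 2 pools allow: how far the pools agreed, which regional and cell type programmes were present, and which gene lists differed between the pools. Values are TPM, a length-adjusted measure of a transcript's share of the library, given as mean ± SD over the 2 libraries (n = 2), or as the pool 1 value followed by the pool 2 value. With 1 library per pool, a difference between the pools has no replicate check and carries no p-value.

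The pools shared most of their expressed genes. A TPM of at least 1 in both libraries was reached by 14297 genes, 12766 of them protein-coding. Tuba1a, an alpha-tubulin of newborn neurons, was the most abundant protein-coding nuclear gene (7491 ± 1005 TPM; chromosome 15, 98949837 to 98953703), followed by the embryonic beta-globin Hbb-y (7376 ± 403), the beta-actin gene Actb (5334 ± 92.8), the thymosin gene Tmsb4x (4526 ± 72.6), the ferritin gene Ftl1 (4221 ± 167) and the alpha-globin Hba-a2 (3990 ± 197). Ppia (3686 ± 269), the histone gene Hist1h2ap (3585 ± 134), the elongation factor Eef1a1 (3582 ± 181) and the microtubule regulator Stmn1 (3236 ± 202) completed the 10 highest. Across the 14942 genes with a mean TPM of at least 1, Pearson's r of log2(TPM + 1) between the libraries was 0.985 and Spearman's rho 0.985; both are across genes, which are not independent replicates. Of genes with a mean TPM above 100, 95% had a pool ratio within 1.22-fold of that of the median gene, against 1.97-fold for genes between 1 and 5 TPM.

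Genes more than 2-fold apart were mainly short or weakly covered. There were 240 of them (1.61%), 139 higher in pool 2 and 101 higher in pool 1, and 46 were protein-coding. Small nucleolar RNAs (47 genes), spliceosomal snRNAs (36), processed pseudogenes (33) and microRNA genes (22) made up most of the rest, and the median gene of the 240 had 2.78 reads per library. Gm23455 (34.0 and 0 TPM), Mir8104 (26.6 and 0), Gm22333 (16.6 and 0), Gm25930 (12.8 and 0) and Gm15899 (15.8 and 1.15) were furthest apart towards pool 1. Gm28911 (0 and 11.8), Gm25641 (0 and 11.8), Gm27419 (0 and 11.3), Rpl21-ps15 (9.19 and 48.1) and Gm22027 (2.43 and 11.4) were furthest apart towards pool 2. Among these 10 genes only Rpl21-ps15 and Gm15899 had more than 10 reads in any library, and both are pseudogenes that share sequence with other genes. The biological coefficient of variation, edgeR's common dispersion expressed as a relative SD, was 0.139 over 17025 genes, a value that genes far apart between the pools raise. Counts of expressed genes kept to within 1.5 times under other settings. The count of 2-fold genes did not, with 468 at a pseudocount of 0.1 and 60 with TMM-scaled expected counts. For the TMM-scaled counts the pseudocount of 1 stood for many reads, which shrinks ratios of weakly covered genes.

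**Figure D1:**
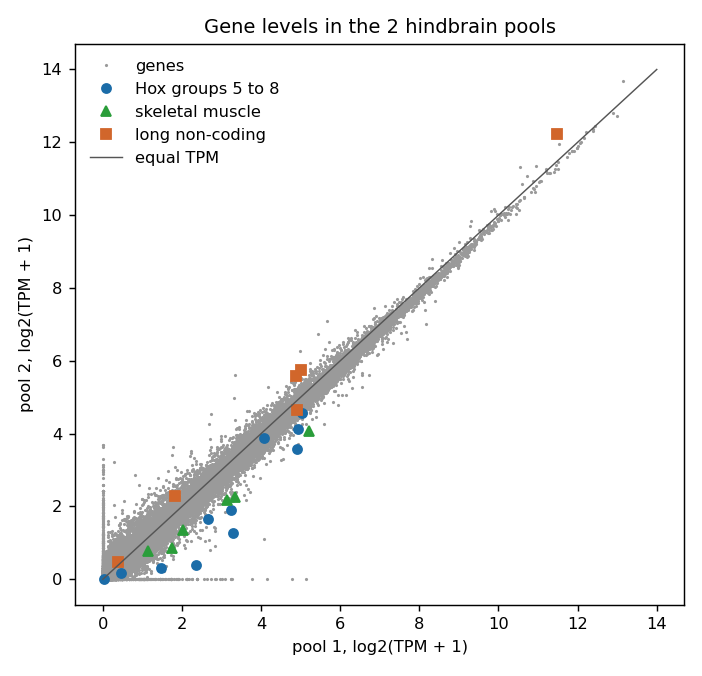
Gene levels in pool 1 (horizontal axis) and pool 2 (vertical axis), both as log2(TPM + 1), with the genes of 3 lists marked and a line at equal TPM. Pearson's r was 0.985 across genes with a mean TPM of at least 1; Hox group 5 to 8 and muscle genes lie below the line, and 4 of the 6 long non-coding genes lie clearly above it.

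Hox genes, which give the hindbrain and spinal cord their positions along the body axis, were read out along their paralog groups. All 12 genes of groups 1 to 4 had a TPM of at least 1 in both pools, against 7 of the 11 in groups 5 to 8 and 0 of the 16 in groups 9 to 13. Summed over each group, transcripts were highest in group 2 (96.4 ± 2.60 TPM) in both pools. Group 3 (56.6 ± 1.43) and group 4 (41.5 ± 0.905) stood level between the pools, while group 5 (77.4 and 53.0) exceeded group 3 in pool 1 only and group 6 stood at 27.3 ± 20.7. Lower sums were found in group 1 (9.63 ± 1.12), group 7 (6.58 ± 5.13), group 8 (3.97 ± 2.40) and group 9 (2.04 ± 1.72). Groups 10 and 13 summed to 0.060 and 0.27 TPM, and groups 11 and 12 had no read.

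Hoxa2 (48.7 ± 0.827 TPM) and Hoxb2 (47.6 ± 1.77) led groups 1 to 4, with Hoxd3 (38.5 ± 1.87) and Hoxc4 (27.1 ± 1.48) next. Hoxa3 (9.94 ± 1.09), Hoxa4 (8.87 ± 0.0919), Hoxb3 (8.18 ± 0.643) and Hoxb1 (5.58 ± 0.856), which marks rhombomere 4 in the segmented hindbrain, were intermediate. Hoxb4 (3.10 ± 0.629), Hoxd4 (2.48 and 2.53 in the pools) and Hoxd1 (1.14 ± 0.163) were lowest. The Hoxa cluster lies on chromosome 6 (52155590 to 52260880), Hoxb on chromosome 11 (96194316 to 96368256), Hoxc on chromosome 15 (102921103 to 103036852) and Hoxd on chromosome 2 (74668310 to 74765142), all on GRCm38. Several annotated Hox genes overlap (Hoxd3 with Hoxd4, Hoxc5 with Hoxc6, and Hoxa3 with Hoxa4, Hoxa5 and Hoxa6), so the split of reads among them is uncertain.

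In groups 5 to 8 the pools were far apart, and 10 of the 11 genes were lower in pool 2 relative to the median gene. Hoxb5 (27.4 ± 6.50 TPM, higher in pool 1), Hoxa5 (29.6 and 16.4), Hoxb6 (29.1 and 11.0) and Hoxc5 (15.8 and 13.8) were the most abundant. Hoxa6 (8.78 and 1.42), Hoxb7 (8.44 and 2.73), Hoxb8 (5.27 and 2.14), Hoxc6 (4.09 and 0.31), Hoxa7 (1.77 and 0.23) and Hoxd8 (0.38 and 0.13) were weaker, and Hoxc8 (0.020 and 0) was at the floor. Hoxb9 (2.43 and 0.56) and Hoxa9 (0.83 and 0.17) differed the same way. Hoxc13 (0.090 and 0.33), Hoxd13 (0.11 and 0.010), Hoxd10 (0.10 and 0.020), Hoxd9 (0 and 0.070) and Hoxc9 (0 and 0.030) had between 0 and 22 reads. Hoxa10, Hoxa11, Hoxa13, Hoxb13, Hoxc10, Hoxc11, Hoxc12, Hoxd11 and Hoxd12 had 0 reads in both libraries, which allows at most 3 counts in each, and the deposited TPM intervals of these 9 genes reached at most 0.466.

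**Figure D2:**
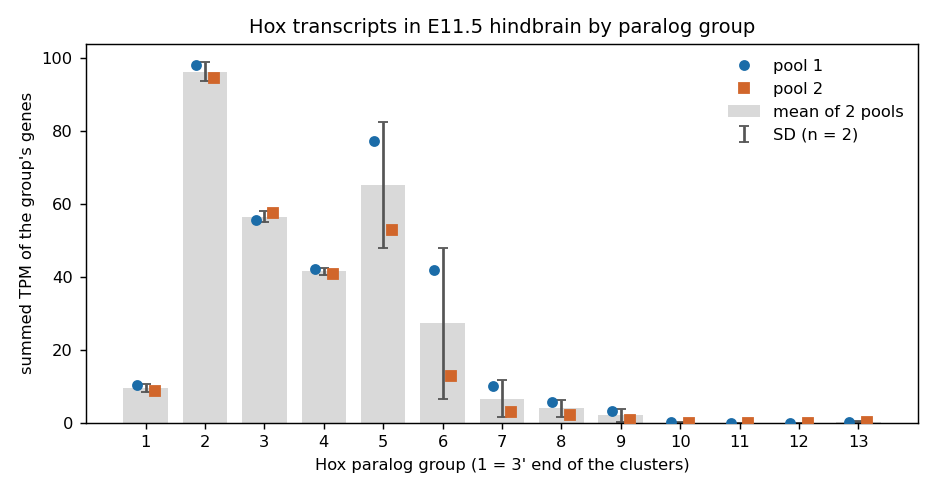
Summed TPM of the genes in each Hox paralog group (bars, mean of the 2 pools; whiskers, SD, n = 2; points, each pool). The pools coincide in groups 1 to 4, and in group 6 they stand at 42.0 and 12.7.

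On the log2(TPM + 1) scale the median of Hox groups 1 to 4 exceeded that of a forebrain list by 2.94 ± 0.04 (n = 2), that of a midbrain and isthmus list by 0.37 ± 0.01 and that of Hox groups 9 to 13 by 3.25 ± 0.04. Against Hox groups 5 to 8 the difference was 0.80 ± 1.17, because it was -0.02 in pool 1 and 1.63 in pool 2. Forebrain regulators were near the floor: 4 of 15 reached a TPM of 1 in both pools, led by Dlx5 (3.14 ± 2.21), Dlx2 (1.67 and 1.34) and Dlx1 (1.31 ± 0.184), while Rax, the eye field gene, stood at 0.045 ± 0.0071. Genes of the midbrain and isthmus, the organiser at the front edge of the hindbrain, were present, with 10 of 11 detected. Cnpy1 (49.2 ± 8.40), Pax8 (17.9 ± 1.81) and Fgf17 (10.9 ± 0.0919) were highest and En2 (0.825 ± 0.092) lowest. Because the size of a log2(TPM + 1) difference involving genes near 0 depends on the pseudocount, the forebrain contrast was 4.68 with a pseudocount of 0.1.

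Patterning genes of the hindbrain itself were abundant. In the rhombomere list 10 of 12 genes were detected, led by the Hox cofactors Meis1 (103 ± 14.6 TPM) and Meis2 (93.8 ± 4.09) and the ephrin receptor Epha7 (46.0 ± 0.509), with Fgf3 (0.59 ± 0.27) lowest. All 12 genes of the rhombic lip and cerebellar anlage were detected, among them Olig3 (38.2 ± 3.68), Zic4 (24.8 ± 0.247), Neurod1 (23.1 ± 1.85) and Barhl2 (1.96 ± 0.771); the roof plate gene Lmx1a stood at 8.57 in pool 1 and 3.86 in pool 2. Dorsal progenitor genes (8 of 9 detected) included Msx1 (80.6 ± 3.81), Msx2 (44.8 ± 1.24) and Pax3 (35.2 ± 1.75), with the roof plate signal Gdf7 lowest (0.725 ± 0.45). Ventral progenitor genes (9 of 11) had a median of 3.25 ± 0.983, about 10 times below the dorsal list at 32.3 ± 4.48; Dbx1 (27.0 ± 0.148), Irx3 (20.4 ± 0.205) and Pax6 (18.2 ± 0.297) were highest and Olig2 (0.75 ± 0.30) lowest.

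**Figure D3:**
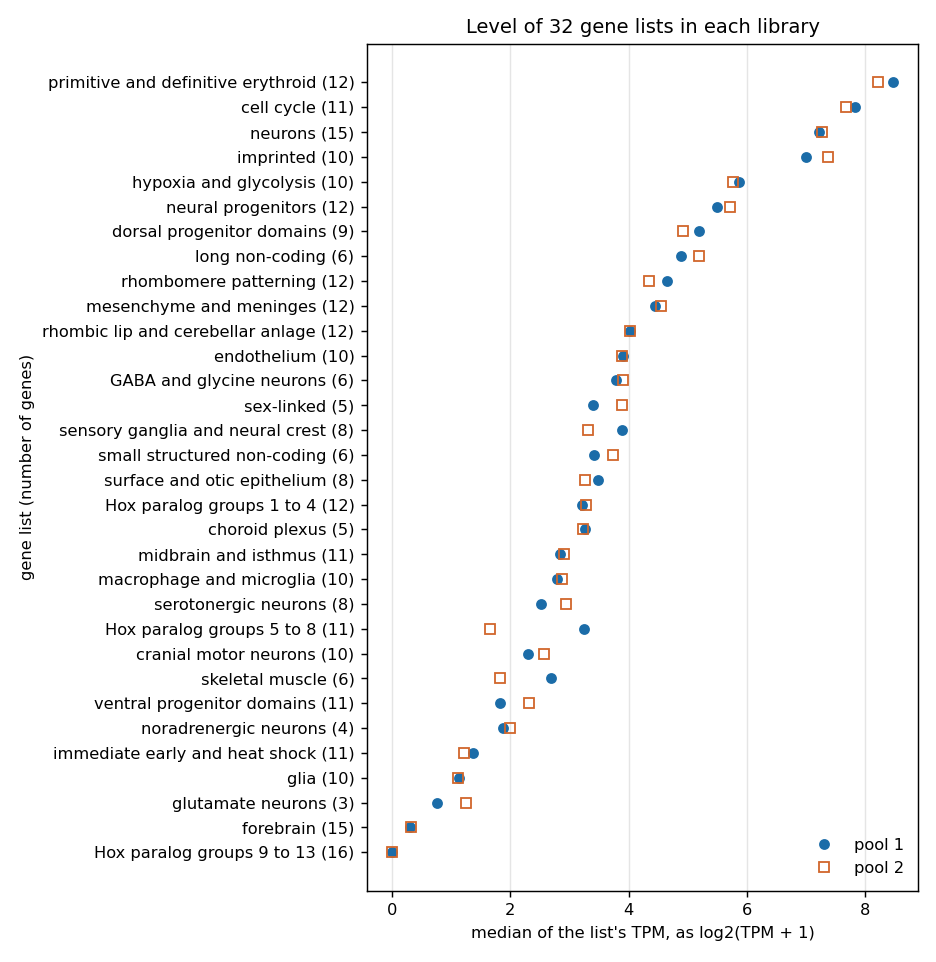
Median TPM of each of 32 gene lists, as log2(TPM + 1), in pool 1 (filled circles) and pool 2 (open squares), with the number of genes per list in brackets. Erythroid, cell cycle and neuron lists are at the top, forebrain and Hox group 9 to 13 lists at the bottom.

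Progenitor and postmitotic programmes were both strongly represented. All 15 neuron genes were detected, with a median of 152 ± 4.44 TPM: Tubb3, the neuronal beta-tubulin, stood at 708 ± 76.3, Stmn2 at 321 ± 26.6, Gap43, a growth cone protein, at 275 ± 23.6 and Rbfox3, a marker of mature neurons, at 8.57 ± 0.148. All 12 progenitor genes were detected, with a median of 47.9 ± 4.97: the intermediate filament gene Vim stood at 1036 ± 25.2, the radial glial gene Fabp7 at 970 ± 65.8, the Notch target Hes5 at 156 ± 65.8 (202 and 109 in the pools) and Sox1 at 3.88 ± 0.134. Sox2, a pan-progenitor factor, stood at 25.2 and 15.4. The neuron list exceeded the progenitor list by 1.66 ± 0.11 on the log2 scale, and all 11 cell cycle genes were detected at a median of 215 ± 16.2, from Cdk1 (265 ± 37.4), Ccnb1 (241 ± 26.6) and Top2a (239 ± 15.9) down to Mki67 (38.2 ± 1.12). The neuron and progenitor difference was 0.85 when list means replaced medians.

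Genes of neurotransmitter programmes were detected at lower levels. The 6 GABA and glycine genes were all detected, led by Lhx1 (39.9 ± 0.445 TPM), Lhx5 (28.7 ± 1.03) and Gad2 (16.6 ± 0.0141), with the vesicular transporter Slc32a1 at 1.70 ± 0.396. Of 3 glutamate transporters, Slc17a6 (22.6 ± 2.59) was detected in both pools and Slc17a8 (0.95 ± 0.61) and Slc17a7 (0.495 ± 0.28) were not. Cranial motor neuron genes (8 of 10) ranged from Isl1 (38.5 ± 9.77) and Isl2 (14.1 ± 5.06) to Mnx1 (0.375 ± 0.19). Serotonergic genes (5 of 8) ranged from Gata3 (14.9 ± 1.28), Slc18a2 (12.6 ± 1.27) and Gata2 (10.3 ± 1.65) to Tph2 (0.79 ± 0.51), the neuronal enzyme of serotonin synthesis. Tph2, Fev and Slc6a4 stayed below a TPM of 1 in pool 1, so the 5 detected genes do not by themselves show serotonergic neurons. Noradrenergic genes (3 of 4) ranged from Th (9.84 ± 0.856) and Phox2a (3.83 ± 0.509) through Dbh (1.82 ± 0.0212) to Slc6a2 (0.25 ± 0.17).

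Mature glial genes were low. Of 10 glial genes 5 were detected, and the list median was 1.18 ± 0.0318 TPM, which is 6.16 ± 0.08 below the neuron list on the log2 scale. Slc1a3 (33.0 ± 2.15), also made by radial glia, and Pdgfra (20.6 and 17.4), also made by mesenchyme, were highest, while Gfap, the astrocyte filament gene, stood at 0.115 ± 0.049.

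Blood, vessels and connective tissue contributed to the pools. The 12 erythroid genes were all detected at a median of 328 ± 41.1 TPM, with Hba-x at 2359 ± 32.8 beside Hbb-y and Hba-a2, and Gata1 at 3.17 ± 0.325. The alpha- and beta-globin genes have near-identical copies, so reads may be split among them. All 10 endothelial genes (Esam 21.7 ± 2.49, Cldn5 20.5 ± 4.40, Emcn 19.6 ± 0.580, Tie1 6.60 and 8.40), all 10 macrophage and microglia genes (C1qb 26.8 ± 1.28, Tyrobp 17.3 and 13.1, C1qc 13.3 ± 0.0707, Ptprc 1.38 ± 0.177) and all 12 mesenchyme and meninges genes (Col3a1 232 ± 15.8, Col1a2 106 ± 11.1, Col1a1 92.6 ± 0.474, Foxc1 6.24 ± 0.0990) were detected. All 8 genes of surface and otic epithelium were detected too, including Krt8 (19.6 ± 1.77), Krt18 (15.8 and 16.1) and Krt5 (1.32 ± 0.106), with Oc90, a gene of the otic vesicle beside the hindbrain, at 105 and 47.6 in the pools. In the choroid plexus list 4 of 5 genes were detected, with Ttr at 194 ± 43.4 and Kl at 0.115 ± 0.092.

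Among other lists, all 10 imprinted genes were detected (Cdkn1c 527 ± 89.4 TPM, Ndn 369 ± 41.7, Meg3 284 ± 34.7, Dlk1 59.1 ± 7.47), as were all 10 genes of hypoxia and glycolysis (Eno1 1156 ± 151, Ldha 1068 ± 193, Pgk1 288 ± 34.1, Vegfa 2.73 ± 1.32). Immediate early and heat shock genes (6 of 11) had a median of 1.45 ± 0.198, from Btg2 (77.3 ± 5.22), Ier2 (44.0 ± 3.31) and Dusp1 (26.7 ± 3.77) to Fosb (0.010 in each). Long non-coding RNAs (5 of 6) were led by Malat1 (3817 ± 1335), Snhg11 (42.2 ± 15.3) and Miat (37.7 ± 13.2), with Neat1 at 0.345 ± 0.064. Small structured RNAs (3 of 6) included Rn7sk (176 ± 5.18), Rpph1 (33.7 ± 3.73) and Rmrp (21.7 ± 3.98), while Rny3 was listed at 0. Mitochondrially encoded genes took 1.21 ± 0.155% of expected counts (1.10% and 1.32%), and the share was 2.39% when computed from TPM. Replication-dependent histone genes summed to 4751 ± 164 TPM, with 50 of 66 genes at a TPM of at least 1 in both pools. Binomial (Wilson) 95% intervals of the mitochondrial, spike-in and Gm42418 read shares were at most 0.00944 percentage points to either side and cover counting error only.

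Between the pools, 9 of 32 lists had a median log2 ratio outside the central 95% of 10000 random lists matched on expression. The number expected would be 1.6 if genes and lists varied independently. Genes of a list can vary together, and some lists share genes (Pax6, Phox2a), so 9 against 1.6 is not a test of chance. Because spike-ins took 16.2% of TPM in pool 1 and 22.2% in pool 2, the median gene had a log2 ratio of pool 2 to pool 1 of -0.11, and ratios below are relative to it. Lists higher in pool 1 numbered 4. Hox groups 5 to 8 had a median relative log2 ratio of -0.89, below all random lists. Skeletal muscle genes had -0.83, also below all random lists, with all 6 lower in pool 2: Actc1, a sarcomeric actin (36.1 and 15.8 TPM), Myog, a myogenic regulator (9.21 and 3.78), Acta1 (7.88 and 3.50) and Myf5 (1.22 and 0.73) among them. Sensory ganglia and neural crest genes had -0.29 (percentile 0.080), with 7 of 8 lower: Pou4f1 (53.1 and 38.1), Eya2 (16.2 and 10.7) and Sox10 (12.7 and 7.31) among them. Choroid plexus genes had -0.35 (percentile 0.040), with Ttr (225 and 163), Kcne2 (17.4 and 10.1) and Clic6 lower in pool 2 relative to the median gene, and Folr1 (8.60 and 8.33) and Kl not.

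Lists higher in pool 2 numbered 5. Long non-coding RNAs had a median relative log2 ratio of 0.69, above all random lists: Malat1 (2872 and 4761 TPM; chromosome 19, 5795690 to 5802672), Snhg11 (31.4 and 53.1), Miat (28.4 and 47.0) and Kcnq1ot1 (2.56 and 3.91) were higher in pool 2, and Hotairm1, which lies in the Hoxa cluster, was not (29.0 and 24.2). The summed shares of RNA classes differed alongside: lincRNA and antisense genes without Gm42418 took 1.38% and 1.75% of expected counts, Gm42418 itself 1.01% and 1.56% and mitochondrial rRNA 0.217% and 0.299%, against 87.5% and 82.9% for protein-coding nuclear genes and 7.41% and 10.7% for spike-ins. The lincRNA and antisense share includes genes of the list, such as Malat1, so it is not independent of the list. Such a share can also rest on a few abundant genes. Gm42418 and mitochondrial rRNA, which lie outside the list, were higher in pool 2 as well. Whether the list differs beyond a library-wide difference between RNA classes was not tested. Sex-linked genes had 0.60 (percentile 99.98): the Y-linked Eif2s3y (17.1 and 37.8), Kdm5d (9.58 and 13.9), Ddx3y (9.23 and 13.8) and Uty (7.90 and 10.9) were higher in pool 2, and Xist, transcribed from the inactive X chromosome, was 23.1 and 19.6. Serotonergic genes had 0.55 (percentile 99.98), with 7 of 8 higher, including Ddc (6.28 and 9.90), Fev (0.95 and 2.07), Slc6a4 (0.58 and 1.40) and Tph2 (0.43 and 1.15). Fev, Slc6a4 and Tph2 were weakly covered, with 34, 45 and 32 reads in pool 1 and 73, 102 and 82 in pool 2. For serotonergic members with a mean TPM of at least 1 the median was 0.34 (percentile 98.85). Cranial motor neuron genes had 0.33 (percentile 99.09), with 8 of 10 higher, while the abundant Isl1 (45.4 and 31.6) and Isl2 (17.7 and 10.6) were lower. Imprinted genes had 0.09 (percentile 99.82), with 7 of 10 higher, led by Grb10 (114 and 173).

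The other 23 lists lay between percentiles 3.38 and 94.2, among them mesenchyme and meninges (85.2, although Dcn stood at 17.9 ± 8.24 TPM and was higher in pool 2), surface and otic epithelium (82.5) and Hox groups 1 to 4 (73.1). For Hox groups 9 to 13 the list median and the bounds of the random lists were all 0, as 9 of 16 genes had no read. That list could not fall outside. When list means replaced medians, the motor neuron list moved to percentile 81.2 and the choroid plexus list to 3.21, inside the central 95%, while mesenchyme and meninges moved to 98.2 and Hox groups 9 to 13 to 1.35, outside it. With TMM-scaled counts the forebrain (0.14), cell cycle (1.01), ventral progenitor (98.6) and GABA and glycine (97.8) lists lay outside too. With DESeq2 size factors the cell cycle list did so (1.08). The direction of each of the 9 lists was the same under the other scalings tried.

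**Figure D4:**
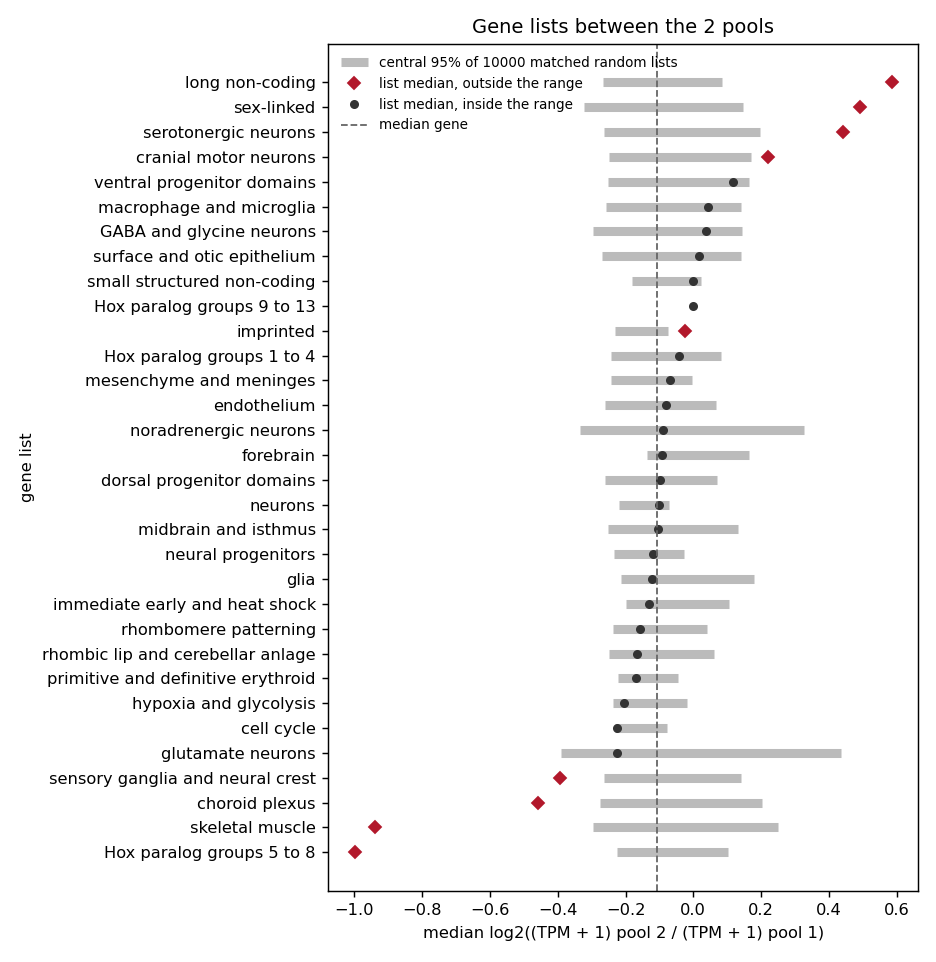
Median log2 ratio of pool 2 to pool 1 for each of 32 gene lists (diamonds and circles), with the central 95% of 10000 random lists matched on expression (grey bars) and the median gene (dashed line, -0.11). The 9 diamonds lie outside their grey bar, 4 to the left and 5 to the right.

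Both pools named the same major transcript for the 10 genes examined that were listed with more than 1 transcript. The share of a gene's TPM in its major transcript had a median of 50.9% over these 10 genes, and of 56.0% over all 12 planned genes, and differed between the pools by a median of 2.08 percentage points over the 10. Pkm, the pyruvate kinase gene with alternative muscle and embryonic forms, had 85.2 ± 0.180%, and Cdc42, with brain-specific and general forms, had 86.4 ± 0.590%. The adhesion genes Ncam1 (72.3 ± 3.03%), L1cam (56.2 ± 1.88%) and Nrcam (55.7 ± 3.79%) followed, then the tau gene Mapt (46.0 ± 0.483%), Numb (43.0 ± 1.34%) and Tpm1 (35.7 ± 0.356%). Map2 had 43.8% in pool 1 and 35.4% in pool 2, the largest gap of the 12 genes (8.35 points). Pax6 had 25.6 ± 1.60%, close to the 24.7 ± 1.90% of its next transcript, and App and Ptbp2 were listed with 1 transcript each. Transcripts of 1 gene share most of their sequence, so these shares rest on how the authors' estimation divided shared reads.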

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

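Signals outside the compared genes were looked at because they exceeded the 3 reads that a count of 0 allows. Spike-ins took 7.41% of expected counts in pool 1 and 10.7% in pool 2, so pool 1 held 12.5 gene reads per spike-in read and pool 2 held 8.32. The same 10 ng of input is given for both libraries. The entries named by a number, which the sources used here do not describe, held 16 reads in pool 1 and 22 in pool 2. No test of either signal was made.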

How the results depend on the processing

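No paired analysis was possible because the series holds 1 group. Scaling without spike-ins, random lists from protein-coding genes, a minimum of 100 reads and isoform shares of genes with more than 1 transcript (median 50.9%, against 56.0% for all 12) were chosen after seeing the data. The cause of a change was not tested except where named. The 6 list contrasts kept their direction under all alternatives except the Hox groups 1 to 4 minus 5 to 8 difference, which was -0.021 from pool 1 alone and 1.63 from pool 2 alone. With a pseudocount of 0.1 the contrasts of Hox groups 1 to 4 with forebrain, with midbrain and isthmus and with Hox groups 9 to 13, and of neurons with glia, were 4.68, 0.42, 6.43 and 6.97. With FPKM they were 2.52, 0.35, 2.74 and 5.85. With TPM over protein-coding nuclear genes, the forebrain, Hox 9 to 13 and glia contrasts were 3.30, 3.72 and 6.38. With list means the forebrain, midbrain and glia contrasts were 2.83, 0.42 and 4.59, and neurons minus progenitors was 0.85. Pearson's r was 0.964 with a pseudocount of 0.1 and 0.994 with no filter. The 240 genes over 2-fold apart became 468 with a pseudocount of 0.1 and 50 at a mean TPM of at least 5. They became 60 with TMM-scaled counts (36 of them among the 240) and 443 with DESeq2 size factors. These 2 counts do not compare the scalings, because the pseudocount of 1 was added on different scales. TMM-scaled counts were relative to library size, so adding 1 stood for many reads and shrank ratios of weakly covered genes. DESeq2-scaled counts stayed near read numbers (size factors 1.06 and 0.946), so adding 1 stood for about 1 read. From fewer genes, the number was 46 among protein-coding genes and 48 with at least 100 reads. The coefficient of variation was 0.151 with no filter, 0.124 for protein-coding nuclear genes and 0.0564 from the median DESeq2 dispersion, which on simulated data came out as 0.0258 for a true 0.1 and so reads low. The mitochondrial share was 2.39% of TPM. The 9 lists outside the central 95% became between 9 and 13, and 7 of the 9 stayed outside under all 7 alternatives. The forebrain list turned to -0.12 with TMM-scaled counts (percentile 0.14), and Hox groups 9 to 13, with Hoxb9 alone left at a mean TPM of at least 1, to -1.03. Limits were 1 SD for means, 1.5 times for counts, 0.005 for r and the coefficient of variation and, for a list, whether it lay outside the central 95%. Of 297 alternative values 258 kept within these limits, 28 passed them, 8 list differences moved outside the central 95%, 2 moved inside, and 1, the Hox contrast from pool 1 alone, turned sign. In all, the sign differed in 21, of which 18 were lists inside the central 95% in both settings, such as glutamate neurons (-0.12, and 0.12 with list means). Depth limits genes with few reads: 4647 genes with 10 to 100 reads had an SD of 0.94 between the pools.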

Other observations

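Genes outside the lists also separated the pools, among protein-coding genes with at least 100 reads in both libraries together, a selection made after the values were seen. Higher in pool 1 were Swi5, a DNA repair gene (287 and 128 TPM), the linker histone gene H1f0 (207 and 95.2), Cop1, a ubiquitin ligase (93.1 and 37.8), the Polycomb gene Phc2 (69.3 and 32.1), the transketolase gene Tkt (60.3 and 26.9) and Trappc3 (29.4 and 12.2). Higher in pool 2 were Taf15 (5.44 and 18.3), Nufip2 (3.71 and 10.4), Htra1 (5.53 and 13.5) and Xrn1 (11.5 and 23.7). Aff4 stood at 30.9 and 76.4 TPM with nearly equal read numbers (6234 and 6363), so its gap lies in the transcript lengths assigned to its reads. Reads of Xrn1 (2017 and 2792) and Htra1 (311 and 499) were also less far apart than their TPM. Relative to the median gene, Cop1 had a log2 ratio of -1.17 in TPM, against -0.83 in TMM-scaled counts. Swi5, H1f0, Phc2 and Tkt lay near -1 in both. Among RNAs of the mitochondria and ribosome, the mitochondrial rRNA mt-Rnr2 stood at 1966 and 2589 TPM and mt-Rnr1 at 510 and 610. Gm42418, annotated as a lincRNA on chromosome 17, took 1.01% and 1.56% of expected counts. Copies of mitochondrial genes on chromosome 1, such as Gm28437 (5332 and 5066 TPM), share reads with the mitochondrial genome and are uncertain.

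The tests in the paragraphs that follow were planned before any result was computed, except the spike-in comparison of deeply covered genes, the length and GC correction and the interval count for Hox genes, the muscle and mesenchyme difference, and the neuron and cell cycle difference, which were chosen afterwards, as were the bootstrap intervals of the correlations. The first pattern is that Hox groups 5 to 8 were lower in pool 2 while groups 1 to 4 stood level. The median log2 ratio of groups 5 to 8 minus that of groups 1 to 4 was -0.95, outside the range of -0.20 to 0.26 of matched random lists. Counting error is argued against, since 8 of 11 genes had separate TPM intervals, all higher in pool 1. Removing the trend on length and GC left -0.92, outside the range of -0.21 to 0.26 of random lists. There was almost no trend to remove (Spearman rho -0.0011 and -0.063 over 14833 genes). These values argue against a library-wide trend on length or GC as the source of the Hox difference. A bias confined to certain genes was not tested. A candidate explanation that the data leave open is that the caudal cut lay further back in pool 1, which the design does not name. The planned test measures the pattern itself. Any cause of a drop in groups 5 to 8 alone would pass it, so it gives this candidate no support of its own.

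The second pattern is that skeletal muscle and sensory ganglia lists were higher in pool 1. The planned prediction for a general excess of surrounding tissue was that mesenchyme and epithelium shift with muscle and ganglia. The epithelium list did not, but it mixes surface and otic genes. Relative to the median gene, 6 of its 8 genes were higher in pool 2 and 2 lower, among the latter the otic gene Oc90 (105 and 47.6 TPM). Of the 4 lists of surrounding tissue, 2 lay beyond the central 95% with lower values in pool 2 (muscle and sensory ganglia). None lay beyond it the other way with list medians. With list means, mesenchyme lay at percentile 98.2, higher in pool 2, with muscle at 0.020 and sensory ganglia at 1.18. Muscle moved away from mesenchyme by -0.87, outside the range of -0.20 to 0.40. This difference, chosen after both medians were seen, cannot decide on an equal carry-over. The mesenchyme list had a median of 21.6 TPM and the muscle list 4, and the same added amount shifts the log2 ratio of a higher list less. Carry-over may therefore remain, of all surrounding tissue or of particular tissue such as muscle precursors or ganglia beside the caudal hindbrain. It cannot be told apart from a difference in the embryos, since each pool is 1 library.

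The third pattern is the set of 240 genes over 2-fold apart. Their log2 ratio had a Spearman rho of -0.055 with GC content (234 genes; bootstrap 95% interval -0.19 to 0.08), below the 0.3 sought, and of -0.15 with effective length (-0.30 to 0.01). Most of these genes had few reads, and among the 10 with at least 1000 reads per library on average the median GC was 52.3% for the 7 higher in pool 1 and 43.9% for the 3 higher in pool 2, so GC and length bias are both left open. Counting error could account for many of them, as TPM intervals overlapped for 74.2%, but for those 10 it is argued against: no spike-in with as many reads lay more than 0.22 from the spike-in median. Of the 10, 6 were also over 2-fold apart in TMM-scaled counts, and Aff4 was not.

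A hypothesis on the sex-linked genes is that pool 2 held a larger share of male embryos. The 4 Y-linked genes had a median relative log2 ratio of 0.62 (0.52 to 1.21) and Xist had -0.12, the directions and sizes set in advance. The Xist difference lies within the spread of genes of its level, 95% of which had a pool ratio within 1.32-fold of the median gene's, so the hypothesis rests on the Y-linked genes. Another hypothesis is that pool 2 was slightly later in development, with more neurons and fewer dividing cells. The neuron list minus the cell cycle list gave 0.12 (percentile 98.6). That difference lay mainly in the cell cycle list (relative log2 ratio -0.12, percentile 3.38, inside the central 95%). The neuron list stood level (0.0085, with 8 genes higher in pool 2 and 7 lower), which shows no gain of neurons. Its level minus that of the progenitor list was 1.74 in pool 1 and 1.58 in pool 2, although the progenitor list's own median ratio was level too (-0.01). The adult beta-globins Hbb-bt and Hbb-bs against the embryonic Hbb-y and Hbb-bh1 gave -0.07, a value without a range from random genes. These readouts do not point the same way and the hypothesis stays open.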
